A study of Mus musculus with 4 samples.

How the data were processed

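RNA from cultured B16-F10 cells, a mouse melanoma line, was compared on 4 Agilent 2-colour whole-genome arrays. On each array the Cy5 channel held cells treated with a goat polyclonal agonist antibody against mouse TIM-3 and the Cy3 channel held cells of the same passage treated with unspecific goat IgG, at 15 ug/ml for 2 h, per the labels. The 4 arrays are biological replicates per the labels and come from passages 14, 16, 18 and 19 of the line. The treatment protocol of the Cy5 sample is not repeated for replicate 3, whose source name gives the anti-TIM3 antibody. No array had the dyes exchanged, so a dye effect of a probe and an effect of the antibody are the same factor in this design. All 4 arrays lay on 1 slide and in 1 scan per the file headers, so slide could not be fitted as a block.

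The deposited scanner files hold linear spot intensity for each channel, with flags, made with Agilent Feature Extraction 9.5.1.1 per the file headers. The submitters' processing notes name Agilent Feature Extraction 9. The deposited value table holds log10 ratios of Cy5 over Cy3 that equal the ratio column of the scanner files for every spot within 1e-06, so its scale and direction are known, and the median of each deposited column over non-control spots was 0. The processed signals in the deposited files were spatially detrended and dye-normalised by the authors' software, per the file headers.

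The mean signal was corrected with the median local background by the normexp method with an offset of 50, and each array was normalised within itself by loess with control spots at weight 0. Outlier spots were left out, and the spots of a probe were averaged. Of 41174 probes, 26545 were tested, those well above background in either channel on at least 3 of the 4 arrays. Log2 ratios of Cy5 over Cy3 were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A log2 ratio above 0 means a higher signal after anti-TIM3. Adjusted p-values below are from this fit unless another test is named. The arrays are few, which limits the precision, and p-values measure the spread between passages of a single line.

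Probes were named through a RefSeq gene table of assembly GRCm38.p6. An accession named 22944 probes, an accession in the probe's list 47, a current symbol 6664 and a synonym 3076, and 8443 kept the name in the files. Coordinates are those of the files, whose headers give the annotation build mm7. The files' chromosome differed from that of the naming gene for 347 of 32632 probes (1.06%). The files do not say in which exon or untranslated region a probe lies.

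Gene lists (21) were fixed before the data were examined. Each gene was represented by its tested probe with the highest mean log2 intensity, and each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The named genes were also set by a rule fixed then. It takes Havcr2, the 10 genes higher and the 10 lower with the largest absolute mean log2 ratio among named genes that passed, had the same sign on all 4 arrays and were well above background in both channels on at least 3. It also takes up to 4 members of each list that passed, and up to 3 genes per direction well above background on all arrays in one channel and on none in the other. Some genes this rule takes are not reported here. For the last group, a bound was computed, where the higher channel was the detected one, after loess and Aquantile normalisation of the separate channels. The bound is the mean of the bright channel over the mean, per array, of the dim probe or the lowest signal among probes well above background, whichever is higher. It is open to dye bias.

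The steps were tested on simulated ratios with the spread of the real probes. Of 66 probes changed by 0.25 on the log2 scale, 56.1% were called among 26545, of 67 changed by 0.5, 97.0%, and of 67 changed by 1, 98.5%, with 9 false calls. A simulated shift of 0.25 in 1 list was called, and 0 of the other 20 lists were. The simulated probes were drawn independently and without a dye effect, so this does not show how the list test behaves where genes are correlated. The correlation estimated in the real data was 0.47 for the ribosomal list. Alternatives covered the background, normalisation, filter, outlier spots, variance prior, array weights, passage, channel pairing, a minimum change of 1.2-fold, the list test and each replicate left out. Trends removed on probe base counts and intensity, and the exclusion of probes over 15 in mean log2 intensity, were added after the data had been seen.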

Results

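The arrays measured transcript levels in B16-F10 melanoma cells after 2 h with an agonist antibody against TIM-3, an immune checkpoint receptor encoded by Havcr2, relative to unspecific IgG, in 4 biological replicates. Each array gave a log2 ratio of the antibody sample (Cy5) over the IgG sample (Cy3) of the same passage. Between 21151 and 22086 of the 41174 probes were well above background in Cy3, and between 25703 and 28400 in Cy5. Across the 26545 tested probes the log2 ratios of different arrays correlated with Pearson's r from 0.524 to 0.746 (probes are not independent replicates). The replicates paired off: r was 0.746 between replicates 2 and 3, 0.707 between 1 and 4, and 0.524 to 0.604 for the other pairs. A dye effect of a probe would also raise r, since Cy5 always held the antibody sample. The 10 spike-in transcripts had mean log2 ratios from -2.54 to 2.82, with SDs over the 4 arrays from 0.05 to 0.17.

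The first question was whether the receptor's own transcript was present and changed. Havcr2 was well above background in both channels on all 4 arrays at a probe on chromosome 11, from 46437901 to 46437960 (mm7). Its log2 ratio was 0.04 ± 0.04 (SD, n = 4; limma, adjusted p = 0.401), with a 95% confidence interval from -0.04 to 0.12. The probe lay at percentile 50.2 of the tested probes by intensity. A second Havcr2 probe, from 46413172 to 46413231, was well above background on 0 arrays in Cy3 and 1 in Cy5 and was not tested. Among the receptor's relatives and ligands, 6 of 8 genes were tested and 1 rose, Hmgb1, which encodes a chromatin protein that TIM-3 can bind (0.13 ± 0.04, adjusted p = 0.0235; 1 adjusted over the list alone). Its other 3 probes had log2 ratios from -0.10 to -0.07, and the ratio of the probe that rose was -0.033 with trends on intensity and base composition removed. Hmgb1 did not pass without replicate 1, 2 or 3 (adjusted p = 0.0601, 0.0697 and 0.0843), nor in the ratios from the deposited processed signals (adjusted p = 0.573). The list as a whole was not called (camera, adjusted p = 0.674).

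The second question was which transcripts differed between the antibody and IgG samples. The genes that rose most included those for ribosomal proteins (Rpl41, Rps23, Rpl7a, Rps18 and Rpl12) and metabolic enzymes (Aldoa and Ldha of glycolysis, and Mdh2, mitochondrial malate dehydrogenase). Those that fell most included Cfl1, which encodes the actin-severing protein cofilin, the translation factor genes Eif5a and Eef2, and the splicing factor gene U2af2. In all, 3776 probes rose and 3600 fell, or 27.8% of those tested. The counts were 2142 and 2080 without replicate 4, and 2219 and 2387 without replicate 2. With all 4 replicates the median absolute log2 ratio of the called probes was 0.17, 27 rose and 9 fell by at least 1.5-fold, and 1 rose and 0 fell by at least 2-fold. These sizes depend on the processing: among the probes called with the deposited processed signals, 556 rose and 85 fell by at least 1.5-fold, and 123 and 3 by at least 2-fold. Among the dimmest tested probes, at 6 to 7 in mean log2 intensity, the deposited ratios ran from -0.39 to 0.86 (5th to 95th percentile). After normexp and loess these probes ran from -0.13 to 0.17. At 10 to 11 the ranges were -0.24 to 0.24 and -0.22 to 0.22. With a normexp offset of 10 in place of 50, 68 rose and 14 fell by at least 1.5-fold, and 4 and 0 by at least 2-fold. The same sign on all 4 arrays was seen for 47.7% of tested probes, against 12.5% by chance. A dye effect of a probe would also repeat its sign, since Cy5 always held the antibody sample. This share therefore does not tell such an effect from one of the antibody.

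Aldoa had the largest ratio, 1.01 ± 0.07 (SD, n = 4; adjusted p = 1.66e-05), at a probe on chromosome 7 from 122891843 (mm7), and its other probe also rose (0.58). Both Aldoa probes were at 17.0 in mean log2 intensity, and of all tested probes over 16, 89.6% rose. Rpl41 (0.84 ± 0.20), Rps23 (0.83 ± 0.15) and Rpl7a (0.82 ± 0.20) followed, with adjusted p-values of 0.00024, 0.000108 and 0.000265. The log2 ratios of Ldha, Rps18, Rpl12, Lrrc58, Mdh2 and Hint1 lay between 0.70 and 0.72. All 10 of these probes were higher on 4 of 4 arrays and had a mean log2 intensity over 16, and in the ratios from the deposited processed signals they had 0.35 to 0.61 and passed. The other tested probes did not always rise with them: the 2 of Rpl7a had -0.11 and 0.02, those of Rps18 ranged from -0.05 to 0.40, and 2 of the 3 of Lrrc58 fell.

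Cfl1 fell by 0.84 ± 0.09 (SD, n = 4; adjusted p = 6.64e-05) at a probe on chromosome 19 from 5388191 (mm7). Eif5a fell by 0.66 ± 0.19 (adjusted p = 0.000466) and Eef2 fell by 0.60 ± 0.23 (adjusted p = 0.00128). Arhgef1, Csrp1, Neat1, the long noncoding RNA of nuclear paraspeckles, Ogfr, U2af2, Tmem242 and Cenpb had log2 ratios between -0.60 and -0.58. These 10 probes were lower on 4 of 4 arrays, and none was over 15 in mean log2 intensity. Of 7 other tested probes of these 10 genes, 6 also fell and 0 rose. Neat1 had the widest spread, with an SD of 0.39, and did not pass in the ratios from the deposited processed signals (adjusted p = 0.0554).

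**Figure D1:**
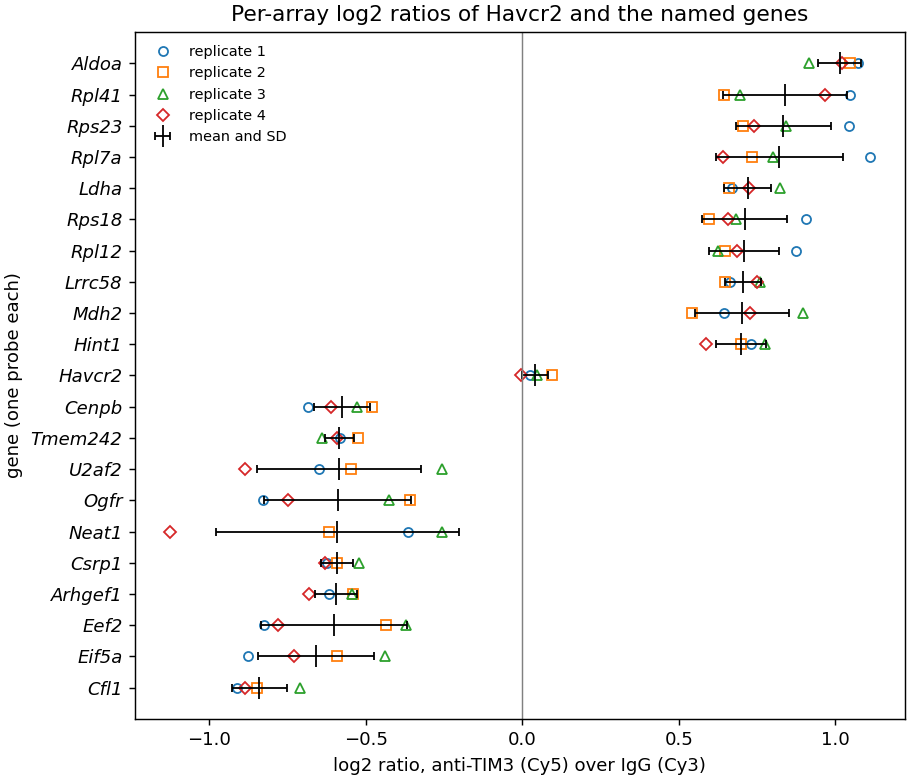
Log2 ratio of anti-TIM3 over IgG (horizontal axis) for Havcr2 and the 10 genes highest and 10 lowest by the fixed rule, 1 probe each (vertical axis). Symbols are the 4 replicates and black bars the mean and SD. Aldoa lies at 1.01, Cfl1 at -0.84 and Havcr2 at 0.04.

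With each array only centred on its median, 0 probes passed (limma; 968 higher and 38 lower at an unadjusted p under 0.05), and the median of all tested probes moved to 0.15. Ier2, Bax, Fkbp4, Trib3, Atf4, Insig1, Cyp51, Tef, Fbln1 and Eng, which fell after loess, had ratios above 0 with that centring but below this median. Mki67, Id3, Calr and Bag3, which also fell after loess, had ratios above it. After loess, Fkbp4, Insig1 and Tef did not pass without replicate 1, nor without replicate 4. Calr did not pass without replicate 3, nor without replicate 4. Fkbp4 and Insig1 also did not pass in the deposited processed signals. With the channels fitted separately, without the pairing within an array, 330 probes rose and 252 fell, and against a minimum change of 1.2-fold 43 rose and 13 fell.

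Among tested probes over 16 in mean log2 intensity, 89.6% rose and 0.549% fell, with a median log2 ratio of 0.34. The same probes had a median of 0.08 in the ratios from the deposited processed signals. Where 2 non-overlapping probes of a gene were both called, they moved in the same direction in 65.1% of 1121 pairs. Gene names with probes called in both directions numbered 303.

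**Figure D2:**
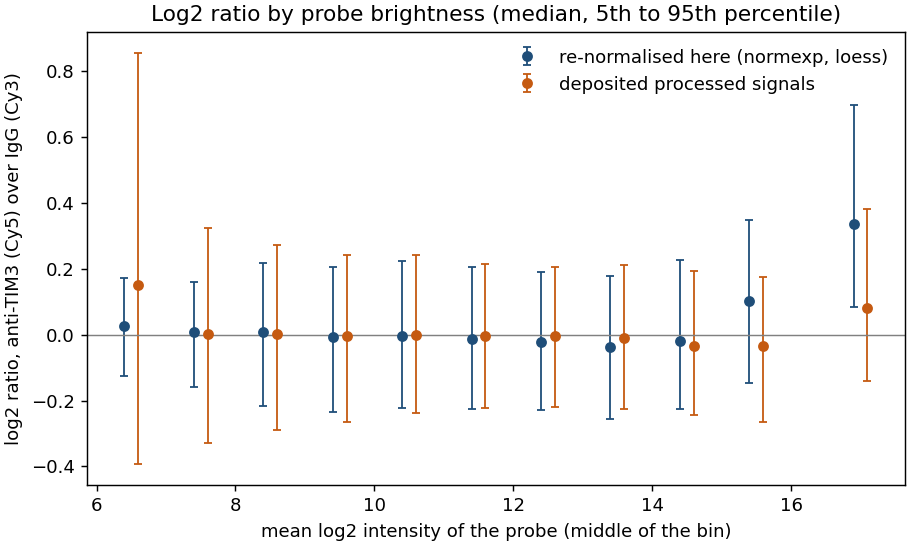
Log2 ratio of anti-TIM3 over IgG (vertical axis) by mean log2 intensity of the probe (horizontal axis). Points are medians of the probes in a bin and bars run from the 5th to the 95th percentile, in blue after normexp and loess and in orange for the deposited processed signals. In the brightest bin the medians are 0.34 and 0.08.

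The third question was whether groups of genes moved together. Of the 21 lists, 4 were called, each upwards: cytosolic ribosomal proteins, hypoxia and glycolysis, melanocyte differentiation and pigmentation, and oxidative phosphorylation. For each of these 4 lists the adjusted p was 0.73 with an estimated correlation. With trends on intensity and base composition removed, a step chosen after seeing the data, the ribosomal (adjusted p = 3.56e-06) and hypoxia (adjusted p = 0.00628) calls held while the melanocyte (adjusted p = 0.109) and oxidative phosphorylation (adjusted p = 0.251) calls ended. The ribosomal median was then 0.15 in place of 0.34, and the hypoxia median 0.14 in place of 0.16. No list was called from the deposited processed signals or among probes up to 15 in mean log2 intensity, where the mean of the ribosomal list was -0.074. Fry, which asks whether the genes of a list move on balance in one direction, called these 4 and also the immediate early genes (adjusted p = 0.018) and the TGF-beta list (adjusted p = 0.00704). The mean log2 ratios of those last lists were 0.047 and 0.045. Fry does not compare a list with other genes, so its calls do not set a list apart from them. A dye effect of the probes could also give such calls.

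Of 56 ribosomal protein genes, 44 rose, 2 fell and 10 did not pass (48 and 2 adjusted over the list alone; camera, adjusted p = 1.99e-18). The median log2 intensity of the list was 16.2. Among all tested probes over 16, 89.6% rose, so this count does not set the ribosomal genes apart from other bright probes. Within this list, which does not hold Rpl41 or Rpl7a, Rps23, Rps18 and Rpl12 had the largest ratios, and Rplp1 rose by 0.60 ± 0.22 (SD, n = 4), but did not pass in the deposited processed signals (0.27, adjusted p = 0.0534). In the hypoxia and glycolysis list 19 of 28 rose and 5 fell, the same numbers as adjusted over the list alone (adjusted p = 0.0003). Ldha rose (0.72 ± 0.07), as did Pgk1 (0.55 ± 0.04), the phosphoglycerate kinase of glycolysis, while Eno1, encoding enolase, fell (-0.55 ± 0.27). The Ldha and Pgk1 probes were over 16 in mean log2 intensity and the Eno1 probe was at 13.4. With trends on intensity and base composition removed, Ldha had 0.46, Pgk1 0.24 and Eno1 -0.50. For melanocyte differentiation and pigmentation 12 of 24 rose and 0 fell, also over the list alone (adjusted p = 0.0065). Mlana (0.58 ± 0.13), Pmel (0.51 ± 0.07), Dct (0.48 ± 0.16) and Tyrp1 (0.41 ± 0.05), all genes of melanosome proteins or pigment synthesis, led the list. All 4 were over 16 in mean log2 intensity, and in the deposited processed signals Pmel (0.19, adjusted p = 0.0552), Dct (0.10, adjusted p = 0.356) and Tyrp1 (0.12, adjusted p = 0.176) did not pass. Tyrp1 also did not pass with trends on intensity and base composition removed (adjusted p = 0.0863). Of 33 oxidative phosphorylation genes 12 rose and 5 fell (13 and 5 adjusted over the list alone; adjusted p = 0.00969), a call that ended without replicate 1 (adjusted p = 0.0882). The ATP synthase genes Atp5b (0.55 ± 0.16) and Atp5c1 (0.46 ± 0.13) rose, but both other probes of Atp5b fell, and Atp5c1 did not pass in the deposited processed signals (0.14, adjusted p = 0.0913).

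**Figure D3:**
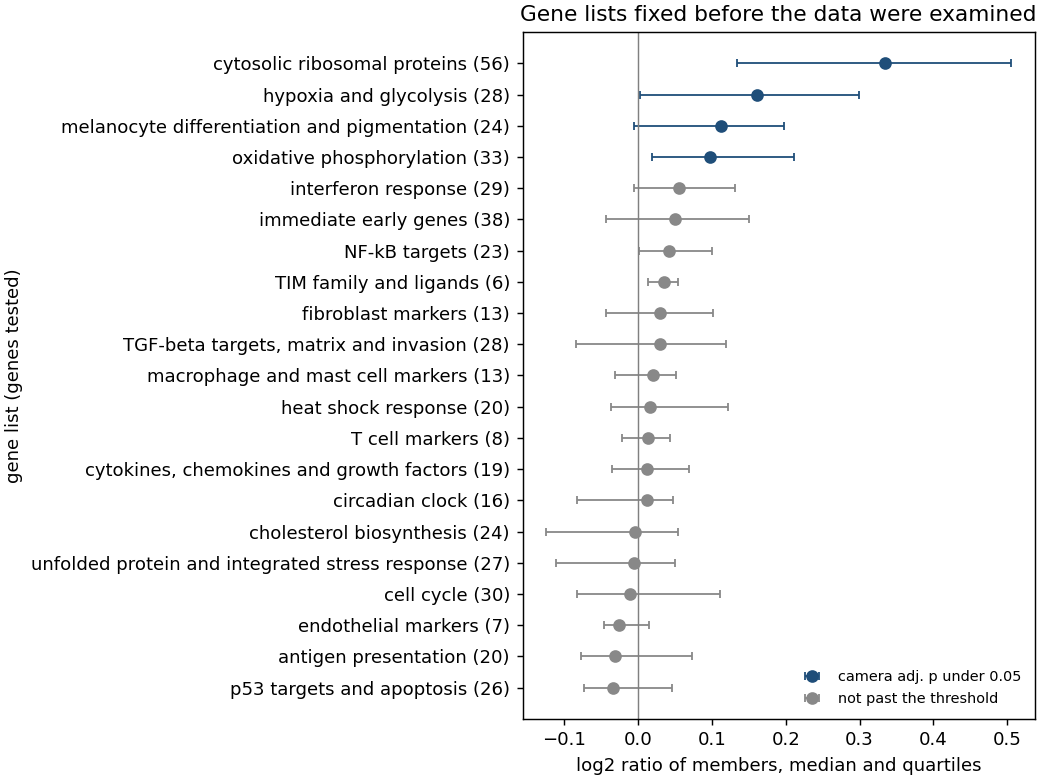
Median log2 ratio and quartiles of the tested members (horizontal axis) of the 21 gene lists (vertical axis, with the number of genes tested). Blue lists passed camera at the preset correlation, and none did with an estimated correlation. The ribosomal list has the highest median, 0.34.

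The remaining lists were not called, though single members moved. Of all tested probes 27.8% were called, so called members are to be expected in any list and do not by themselves mark a response of it. Of 38 immediate early genes, which respond first to many stimuli, 12 rose and 2 fell (13 and 2 adjusted over the list alone; camera, adjusted p = 0.183). Junb (0.35 ± 0.05), Maff (0.21 ± 0.03) and Egr1 (0.20 ± 0.04), which encode transcription factors, rose, and Ier2 fell (-0.26 ± 0.08). The other tested Ier2 probe had 0.03 and did not pass. Among 23 NF-kB targets 5 rose and 0 fell, also over the list alone (adjusted p = 0.326): Nfkb1 (0.25 ± 0.10) and the chemokine genes Cxcl10 (0.20 ± 0.11) and Cxcl1 (0.16 ± 0.12) were among them, and 1 other Nfkb1 probe fell. Cxcl1 did not pass without replicate 2 or 4 (adjusted p = 0.115 and 0.138). Of 29 interferon response genes 5 rose and 1 fell (3 and 0 adjusted over the list alone; adjusted p = 0.326), with Oasl2 at 0.25 ± 0.12 and Gbp2 at 0.20 ± 0.08. The mean of this list was 0.24 in replicate 2 and from -0.03 to 0.05 in the others, and Oasl2 had 0.43 in replicate 2 and 0.16 to 0.21 in the others. The list was called without replicate 3 (adjusted p = 0.0221) and not without replicate 2 (adjusted p = 0.916). Of 19 cytokine, chemokine and growth factor genes 3 rose and 1 fell, also over the list alone (adjusted p = 0.726), including Il33 (0.25 ± 0.04), a cytokine of the interleukin-1 family.

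In the unfolded protein and integrated stress response list 3 of 27 rose and 6 fell (4 and 6 adjusted over the list alone; camera, adjusted p = 0.657), and the mean of the list was -0.03, or 0.40 with median centring, where all tested probes had a median of 0.15. With that centring the list was called upwards (camera, adjusted p = 0.0039), as 1 of 12 lists called. Atf4, the main transcription factor of the integrated stress response, fell (-0.29 ± 0.05), as did its target Trib3 (-0.39 ± 0.03). Asns, of the same list, rose (0.19 ± 0.05), though it did not pass in the deposited processed signals (0.01, limma, adjusted p = 0.803). Of 20 heat shock genes 5 rose and 3 fell, also over the list alone (adjusted p = 0.657), with Hspd1, a mitochondrial chaperone gene, at 0.39 ± 0.06 and Bag3 at -0.24 ± 0.03. The second Hspd1 probe fell, and the first did not pass in the deposited processed signals (0.15, adjusted p = 0.0933) or with trends removed (0.14, adjusted p = 0.0612). Of 26 p53 target and apoptosis genes 2 rose and 4 fell (2 and 3 adjusted over the list alone; adjusted p = 0.657). The genes of the proapoptotic protein Bim, Bcl2l11 (0.31 ± 0.07), and of Bax (-0.29 ± 0.09) moved apart. Of 30 cell cycle genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.726). Their median was -0.01 and their mean 0.02. Pcna, the replication clamp gene, rose (0.41 ± 0.03) and Mki67 fell (-0.19 ± 0.12), but did not pass without replicate 1 (adjusted p = 0.0539) or in the deposited processed signals (adjusted p = 0.0779).

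Among 28 TGF-beta target, matrix and invasion genes 7 rose and 2 fell (11 and 6 adjusted over the list alone; camera, adjusted p = 0.657), with Timp2, a metalloproteinase inhibitor gene, at 0.47 ± 0.12, Smad7 at 0.28 ± 0.13 and Id3 at -0.22 ± 0.05. Id3 did not pass in the deposited processed signals (adjusted p = 0.0515). Of 20 antigen presentation genes 1 rose and 3 fell (0 and 2 adjusted over the list alone; adjusted p = 0.657), and Tap1, the peptide transporter gene, was at -0.24 ± 0.12, with an adjusted p of 0.0724 in the deposited processed signals. In cholesterol biosynthesis 5 of 24 rose and 6 fell, also over the list alone (adjusted p = 0.657). The list mean was -0.011, or 0.39 with median centring, where the list was called upwards (camera, adjusted p = 0.0039). Stard4 was at 0.30 ± 0.11, but its other 2 tested probes had -0.10 and -0.08 and did not pass. Cyp51 was at -0.22 ± 0.08, and of its other 2 tested probes 1 fell (-0.12) and 1, at 0.09, did not pass. Of 16 clock genes 1 rose and 3 fell, also over the list alone (adjusted p = 0.657). Their median was 0.01 and their mean -0.03, and Per1 fell (-0.35 ± 0.06).

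Markers of other cell types were examined too. Of the 16 T cell markers 8 were tested, 1 rose and 1 fell, also over the list alone (camera, adjusted p = 0.931). The one that fell, Cd8b1, rests on a probe the files place on chromosome 5, while its other probe lies on chromosome 6 and rose, and it did not pass without replicate 4 (adjusted p = 0.0587). Of 21 macrophage and mast cell markers 13 were tested, 2 rose and 1 fell, also over the list alone (adjusted p = 0.827), with Tyrobp, an adaptor of myeloid receptors, at 0.33 ± 0.09. Of 13 fibroblast markers 2 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.726), and Fbln1 was at -0.21 ± 0.10, with an adjusted p of 0.0656 in the deposited processed signals. Of 7 endothelial markers 1 rose and 1 fell, also over the list alone (adjusted p = 0.657), with Eng at -0.24 ± 0.08.

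Of the called probes of named genes, 312 were well above background on all 4 arrays in Cy5 and on none in Cy3, of which 227 had a ratio above 0 and 85 below, and 0 were detected in Cy3 alone. By the computed bounds, Aspm, which encodes a mitotic spindle protein, had at least 1.12-fold more signal in the anti-TIM3 channel (adjusted p = 0.000836). Olfr1061 had at least 1.32-fold more (adjusted p = 0.00166), and Serpinb12 was also higher, by a smaller bound (adjusted p = 0.00312). These bounds are open to dye bias, and every array had more probes above background in Cy5 than in Cy3. Of the other 2 tested Aspm probes, 1 rose (0.16) and 1, at 0.03, did not pass. Dlg4 (-0.34 ± 0.13, adjusted p = 0.00231), Tbcel (-0.31 ± 0.22, adjusted p = 0.0141) and Khdc1a (-0.30 ± 0.25, adjusted p = 0.0222) had ratios below 0 although they were detected in Cy5 alone, so these values rest on a Cy3 signal not above background and give no bound. Khdc1a did not pass without replicate 2 or 3 (adjusted p = 0.0662 and 0.0532), and neither it nor Tbcel passed in the deposited processed signals (adjusted p = 0.152 and 0.0595). Of the other tested probes of Tbcel, 1 fell and 1 rose.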

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

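Of 126 results examined for an array far from the other 3, 5 stood out, against about 5% expected by chance. Nfkb1 had a log2 ratio of 0.090 in replicate 1 and 0.28 to 0.31 in the others. Snai2 had 0.15 in replicate 3 and 0.19 to 0.20 in the others. Trib3 had -0.44 in replicate 4 and -0.38 to -0.37 in the others. Serpinb12 had 0.79 in replicate 4 and 0.32 to 0.38 in the others, but it was detected in Cy5 alone, so these ratios rest on a Cy3 signal not above background. The 99.9th percentile of the Cy3 signal was 85493 in replicate 1 and 46800 to 49212 in the others.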

How the results depend on the processing

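Trend removal and the limit of 15 in mean log2 intensity were chosen after seeing the data. The probe counts stayed within 1.5-fold of 3776 higher and 3600 lower except in the following. There were 2378 lower probes with the deposited processed signals and 2382 with the deposited ratios, of which 1913 and 1917 were among the main ones. With median centring 0 were higher and 0 lower, and the median standard error was 0.20 against 0.04. Separate channels with no replicate block gave 330 and 252, and a minimum change of 1.2-fold 43 and 13, by its construction. Without each replicate in turn the counts ran from 2142 to 3515 higher and from 2080 to 2736 lower. They were 2142 and 2080 without replicate 4, and 2219 and 2387 without replicate 2. The log2 ratio of Havcr2 ran from 0.02 to 0.06 with a replicate left out, was -0.02 with the deposited ratios and 0.21 with median centring, and passed under none of the 21 settings. The 4 list calls became 0 with an estimated correlation, with the deposited processed signals, with the deposited ratios and among probes up to 15 in intensity, 2 with intensity and base composition trends removed (those of the melanocyte and oxidative phosphorylation lists ended), and 12 with median centring. Leaving out a replicate gave 3 to 5: the call of oxidative phosphorylation ended without replicate 1, as it did without background subtraction, and the interferon list was called without replicate 3. With no filter on dim probes 5 lists were called, the same 4 and 1 more.

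With median centring the median of all tested probes was 0.15, and 15 of the called genes reported changed sign against 0: Ier2 (0.070), Mki67 (0.34), Bax (0.15), Id3 (0.22), Calr (0.40), Fkbp4 (0.15), Bag3 (0.16), Trib3 (0.038), Atf4 (0.10), Insig1 (0.048), Cyp51 (0.13), Tef (0.15), Fbln1 (0.15), Col3a1 (-0.012) and Eng (0.074). Of the 14 that had fallen, 10 stayed below that median. The sign also changed for the means of the unfolded protein response (0.40) and cholesterol biosynthesis (0.39) lists, and both were called there (camera, adjusted p = 0.0039 for each). The camera direction of the macrophage and mast cell markers turned downwards there, with a mean of 0.013 below the median of all probes, and that list was called too (adjusted p = 0.0144). Median centring leaves trends with intensity in place. The median log2 intensity was 13.3 for the unfolded protein response list, 12.8 for cholesterol biosynthesis and 7.1 for the macrophage and mast cell markers. Hmgb1 changed sign with trends removed (-0.033), and the ribosomal list among probes up to 15 (-0.074). The cause was not tested. Of 96 named probes, 33 no longer passed with the deposited processed signals and 58 with separate channels. Slide as a block was not run, since all arrays shared 1 slide. Dim probes are limited by signal over background.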

Other observations

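The test over sign patterns, the removal of trends and the selection of genes with 2 probes were chosen after the results were seen. Genes with 2 non-overlapping probes that both passed with an absolute log2 ratio over 0.3, and no called probe in the other direction, numbered 24, of which 13 fell and 11 rose, and 6 genes had such probes in opposite directions. The splicing factor genes U2af2 and Srsf1 were among those that fell (mean of called probes -0.54 and -0.34), as were Eif5a (-0.52), Aph1a (-0.56), a subunit gene of gamma-secretase, and Gabarap (-0.40), a gene of autophagy. Among those that rose were the mitotic kinesin gene Kif20b (0.46), the spectrin gene Sptbn1 (0.33), the ferritin light chain gene Ftl1 (0.62) and Dct (0.55). A probe over 15 in mean log2 intensity was held by 7 of the 11 genes that rose, Ftl1 and Dct among them, and by 0 of the 13 that fell.

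In all, 7376 probes passed after normexp with an offset of 50, 27 higher and 9 lower by at least 1.5-fold, against 556 and 85 of those called with the deposited processed signals. The deposited ratios spread more widely among the dimmest probes. After a linear trend on the probe's base counts was removed from each array, 6563 probes passed, 5575 of them among the 7376 and in the same direction. This argues against such a trend as the whole source of the calls. Base counts accounted for 8.4% of the variance of the mean log2 ratio, and other effects of the probe sequence were not tested. A dye effect particular to each probe stays open and may account for many of the calls: when 1 probe was called, a non-overlapping probe of the same gene had the same sign in 57.6% of 6916 comparisons with trends removed, against 98.3% computed for 2 probes that change alike and 50.8% where neither was called, both with trends removed. Misnamed probes and different transcripts of a gene would lower that share too. Its binomial 95% interval, 56.4% to 58.8%, lies above the 50.8% but is too narrow. It counts each of the 1121 pairs with both probes called 2 times, and it treats pairs that share a gene as independent. The 98.3% takes the ratio of the called probe as the change of both probes. That probe was picked for passing, so the 98.3% may be too high. The 4 arrays allow 8 sign patterns, too few for a share under 0.05; the real pattern called 7376 probes and the highest of the others 0, so that 1 of the 8, the real pattern itself, called as many.

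The brightest probes were higher in the Cy5 channel. For the 163 probes over 16 in mean log2 intensity that rose, the median was 0.37, while 44 dimmer probes of the same genes had a median of -0.12, so the brightness of the probe rather than the gene may set the direction. The curve fitted within each array at the end of the intensity range cannot be told apart from it: the same bright probes had a median of 0.10 in the deposited processed signals, between the bounds set before the test. An effect of the antibody on these genes was not tested apart from the dye, since no array had the dyes exchanged. Among probes up to 15 in mean log2 intensity, none of the 4 lists was called, and the mean of the ribosomal list was -0.074.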
